A study of Mus musculus with 8 samples.

How the data were processed

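Gene expression was measured by paired-end RNA sequencing of ventricles of mice with floxed Esrra and Esrrg, in 4 libraries labelled AAV-Cre and 4 labelled AAV-Luc. Per the labels' protocols, libraries were made from poly(A)-enriched RNA and sequenced in a single lane. The protocols name both an Illumina TruSeq and a NEBNext Ultra kit and do not say which library had which. The deposited values are RPKM, that is reads scaled by the length of the gene in kilobases and by the total of the library, in a table of 54429 rows. Per the submitters' processing notes, FastQC 0.11, STAR, Partek 6.6, edgeR and the mm10 build were used. The order and role of these tools, the annotation, the gene lengths and the use of strand are not given in the sources used here.

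The 8 columns of values carry the name of a group and no sample title. Each was used as a replicate of its group, without a link to a particular sample. The averages of each group that the authors deposited equal the means of the 4 columns to within 3.64e-12 RPKM. No value above 0 was the same in 2 libraries, so none appeared to be a copy of another. Of the symbols, 98.8% were found in GENCODE release M21 (GRCm38, the same assembly as mm10), from which positions and overlaps of genes were taken. The symbols of 26 rows had been turned into dates, and none of these is named. In 17917 rows all 8 values were 0.

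Depth was estimated from the steps of the RPKM values. In genes with a single annotated transcript, low RPKM values multiplied by the transcript length were whole multiples of 1 step, within 0.1 of a whole number, for 98.8 to 99.2% of values. With 1 step taken as a single read, these imply totals of 48365000 to 61353000 per library. On that scale 1 RPKM in a gene of 1 kilobase corresponds to 48.4 to 61.4 reads. Of these low multiples, 74.1 to 79.3% were even, which counting both reads of a pair would give. The totals therefore appear to count single reads rather than pairs, so independent fragments would be fewer. The step depends on gene length, and the lengths used by the authors are unknown for genes with several transcripts, so counts were not rebuilt and no count model was fitted. The RPKM of 7 pseudogene rows on chromosome 1 lay within 10% of mitochondrial genes. Gm13054, antisense to Nppa, had a log2 fold change of 5.76, beside 5.78 for Nppa. Genes that overlap or have near-identical copies are therefore uncertain. RPKM is relative to the total of a library, so a fall in abundant transcripts raises the values of all others.

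Genes with at least 1 RPKM in at least 4 libraries were tested with limma 3.58.1 in R 4.3.3, on log2(RPKM + 0.5), with a moderated variance that follows the mean level (lmFit and eBayes with a trend). P-values were adjusted by the Benjamini-Hochberg method over the 16385 genes tested, with a threshold of 0.05. The pseudocount makes fold changes of low genes smaller than the ratio of their RPKM. The targeted genes were also compared by a two-sided exact permutation test over the 70 arrangements of 4 and 4. A set of 34 gene lists was tested with camera at a preset correlation between genes of 0.01, and 32 of them had at least 3 measured members. Camera compares a list with all other genes, and fry asks whether the genes of a list move one way on balance. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and plots.

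The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later. The rule named the receptors Esrra, Esrrg and Esrrb, a panel of 20 heart and metabolic genes, and the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 RPKM and no overlap between groups. From the last 2 sets, symbols of unnamed gene models and pseudogenes were left out. It also named up to 3 members with the smallest p of each list that passed in camera or that holds markers of other cell types, handling or targets. A few genes that the rule named are not reported here. Gm13054, Gm44502 and Gnas are named only because they overlap such genes.

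The tests were repeated with pseudocounts of 0.1 and 1, no filter and a mean of at least 5 RPKM, quantile normalization, centring each library on its median, leaving out mitochondrial and haemoglobin genes with rescaling, a robust variance prior, library quality weights, leaving out each library in turn, an estimated correlation in camera, and fry. On data simulated for this comparison over 16385 genes, limma recovered 64% of 50 genes changed by 0.5 on the log2 scale, 94% of 50 changed by 1, and 100% of 50 changed by 2 and of 50 changed by 4. It called 13 unchanged genes, and camera gave an unadjusted p under 0.05 to 1 of 200 random lists. The simulated genes were drawn independently of each other. That rate therefore does not describe lists of correlated genes, such as the tricarboxylic acid cycle, with an estimated correlation of 0.671.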

Results

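RNA was sequenced from mouse heart ventricles at postnatal day 35, in a C57BL/6 line whose genes for estrogen-related receptor alpha (Esrra) and gamma (Esrrg) carry loxP sites. These receptors are transcription factors of mitochondrial and metabolic genes. The mice had received an adeno-associated virus (AAV) on postnatal day 0 to 1. In 4 libraries, labelled AAV-Cre, the virus expressed Cre recombinase from the cardiac troponin T promoter, which is active in cardiomyocytes. In the other 4, labelled AAV-Luc, it expressed luciferase. The comparison asks how gene expression after birth differs when both receptors are targeted in the heart muscle. Library totals implied by the smallest steps of the RPKM values ran from 48365000 to 61353000, and appear to count single reads rather than pairs. Their means were 56674000 ± 3136000 for AAV-Cre and 56384000 ± 5679000 for AAV-Luc (SD, n = 4 each). Library numbers below are names only, given by column order. The labels do not say whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may be partly technical.

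The targeted genes were examined first. Esrrg, on chromosome 1 from 187608791 to 188214885 of mm10, measured 217.9 ± 17.7 RPKM in the libraries labelled AAV-Cre and 112.7 ± 5.51 in those labelled AAV-Luc (SD, n = 4 each), a ratio of 1.93. Its log2 fold change was 0.95 (SE 0.07, limma adjusted p = 5.32e-06), and every AAV-Cre value lay above every AAV-Luc value (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). Esrra, on chromosome 19 from 6910977 to 6921813, measured 39.05 ± 4.66 against 45.09 ± 3.66 RPKM. Its log2 fold change of -0.21 (SE 0.10) did not pass the threshold (limma adjusted p = 0.0705, exact permutation p = 0.143). With each library centred on its median, Esrra was lower in AAV-Cre (log2 fold change -0.62, adjusted p = 0.000549), and Esrrg stayed higher (0.54, adjusted p = 0.000317). The related receptor Esrrb, which was not targeted, measured 3.213 ± 0.545 against 4.538 ± 0.837 RPKM (log2 fold change -0.44, limma adjusted p = 0.017, exact permutation p = 0.0571). RPKM is summed over a whole gene, and the sources used here do not say which exons were floxed. These values therefore do not show whether the floxed exons were lost, and the direction of Esrrg goes against its label. The groups are called by their labels throughout for that reason.

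Expression differed between the labels across most of the transcriptome. Of 16385 genes tested, 12013 (73.3%) passed an adjusted p of 0.05 in limma, of which 10559 were higher and 1454 lower in the libraries labelled AAV-Cre. A change of 2-fold or more was found in 1748 genes, 1454 higher and 294 lower. The whole distribution was shifted: the median log2 fold change was 0.41, a factor of 1.33. After centring each library on its median, 3578 genes were higher and 3949 lower, so that the share of higher calls went from 87.9% to 47.5%. All 3578 were also higher as deposited, all 1454 genes lower as deposited stayed lower, and 182 went from higher to lower. Centring lowers the log2 fold change of every gene by the same amount, so falls grow and rises shrink. That agreement was therefore largely fixed in advance. With centring, 560 genes rose and 737 fell by 2-fold or more. In 10823 genes (66.1%) the groups did not overlap, against 2.86% by chance. That count is of RPKM as deposited, where the shift of the whole distribution can also separate the groups. The first principal component held 77.2% of the variance and separated the groups, and the correlation of libraries was 0.981 to 0.992 within groups and 0.931 to 0.954 between them. Below, "rose" and "fell" refer to RPKM as deposited, and counts after centring follow. Fold changes are on the log2(RPKM + 0.5) scale, which understates those of low genes.

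**Figure D1:**
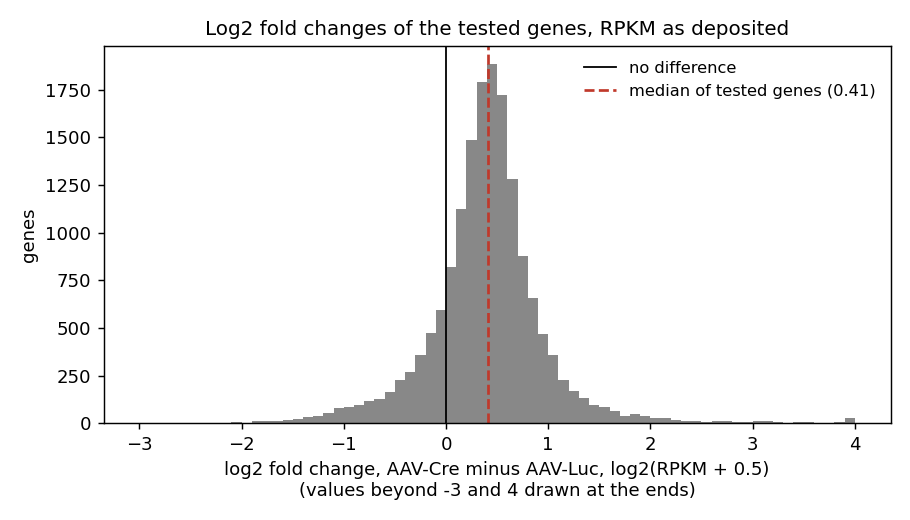
Log2 fold changes of the 16385 tested genes (x axis, AAV-Cre minus AAV-Luc on the log2(RPKM + 0.5) scale) against the number of genes (y axis). The solid line marks 0 and the dashed line the median of 0.41, and most genes lie to the right of 0.

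Nuclear genes for mitochondrial energy metabolism fell in the libraries labelled AAV-Cre. All 24 measured genes of the tricarboxylic acid cycle and pyruvate entry fell, with a median log2 fold change of -1.15. Idh3b, a subunit of NAD-dependent isocitrate dehydrogenase, measured 90.75 ± 9.15 against 263.7 ± 15.1 RPKM, and Suclg1 and Fh1 had log2 fold changes of -1.38 and -1.15. Of 24 genes for fatty acid uptake and beta-oxidation, 19 fell and 1 rose. The thiolase gene Acaa2 measured 97.87 ± 10.7 against 298.8 ± 19.4 RPKM, and Echs1, Etfa, Cpt1b, Acadm and Hadha had log2 fold changes of -1.54, -1.23, -1.08, -0.90 and -0.95. Cpt1b shares 81.4% of its exon bases with the annotated transcript Gm44502, so its reads cannot be fully separated. In respiratory complex I, 35 of 37 genes fell and none rose (median -0.80), among them Ndufs1 (191.4 ± 16.5 against 408.9 ± 12.1 RPKM), Ndufa9 and Ndufv2. In complexes III and IV with cytochrome c, 21 of 23 fell and none rose (median -0.96). Cox7a1, the muscle form of a complex IV subunit, went from 638.9 ± 120.0 to 188.9 ± 36.1 RPKM, and Cox5a, Uqcrc2 and Cox6b1 had log2 fold changes of -1.48, -1.12 and -1.10. Of 20 genes for ATP synthase and ADP exchange, 19 fell and none rose (median -0.85), with Atp5a1 at 521.7 ± 59.4 against 1089.0 ± 55.2 RPKM. Atp5f1 and Atp5h had log2 fold changes of -0.86 and -0.87, and Atp5c1 went from 555.7 ± 24.8 to 278.0 ± 11.3 RPKM. After centring, all members of these lists fell except 1 of the 24 fatty acid genes, which was not called. As centring lowers every fold change alike, this adds no separate evidence for the falls.

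All 13 protein-coding transcripts of the mitochondrial genome fell (median -0.78), and mt-Cytb measured 9195 ± 233 against 17380 ± 840 RPKM. The log2 fold changes of mt-Nd6 and mt-Nd5 were -1.13 and -1.03. Mitochondrial genome reads made up 14.4% ± 0.45 of the implied total in AAV-Cre and 24.6% ± 1.65 in AAV-Luc. The level of these shares is uncertain, because the same product of RPKM and length summed to 196.8 to 231.1% over all genes. Of 18 genes for ketone body and branched-chain amino acid catabolism, 17 fell and none rose (median -0.89), with log2 fold changes of -1.32, -1.30 and -0.86 for Mccc1, Dbt and Bckdhb. The mitochondrial ribosome list was mixed, with 18 of 33 genes lower and 7 higher, or 26 lower and 1 higher after centring. Mrps35, Mrpl9 and Mrpl34 had log2 fold changes of -1.10, -0.53 and -0.92. Of 20 mitochondrial regulators and dynamics genes, 8 fell and 7 rose, or 13 and 2 after centring. Ppargc1a, a coactivator of the estrogen-related receptors, rose from 23.43 ± 2.43 to 103.4 ± 10.2 RPKM (log2 fold change 2.12, SE 0.09, limma adjusted p = 2.99e-07). The mitochondrial superoxide dismutase Sod2 and the fusion gene Mfn1 fell, by -1.57 and -1.44 on the log2 scale. With camera at a preset correlation of 0.01, each of these 9 lists was lower than other genes, at adjusted p = 1.54e-37 for the tricarboxylic acid cycle, 3.58e-24 for fatty acids, 1.14e-42 for complex I, 2.27e-31 for complexes III and IV, 1.09e-26 for ATP synthase, 3.12e-19 for the mitochondrial genome, 9.56e-27 for ketone bodies and branched-chain amino acids, 3.06e-12 for the mitochondrial ribosome and 7.59e-05 for the regulators. With an estimated correlation none of these calls held, since the adjusted p was 0.0834 for fatty acids, 0.0944 for the mitochondrial genome, 0.174 for the mitochondrial ribosome, 0.104 for the regulators and 0.0782 for each of the other 5 lists. The call of the mitochondrial genome list also ended with quantile normalization (adjusted p = 0.431). Counts adjusted over the list alone equalled those over all genes for every list except glucose, endothelial and interferon genes, whose counts are given with them.

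**Figure D2:**
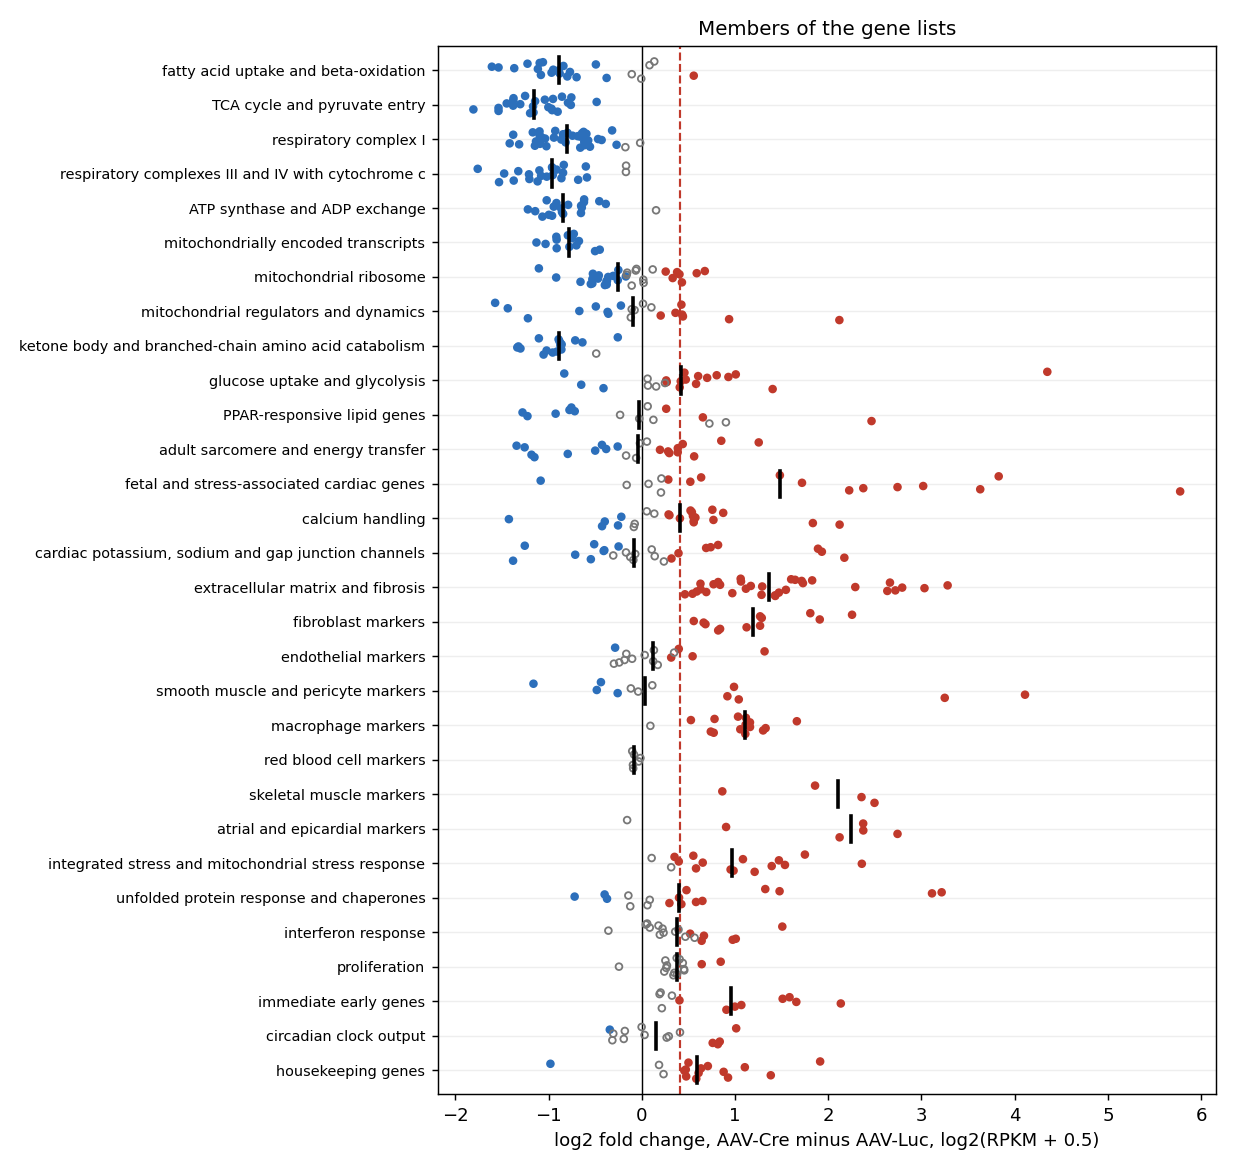
Log2 fold change (x axis, AAV-Cre minus AAV-Luc on the log2(RPKM + 0.5) scale) of each measured member of the gene lists (y axis). Red and blue points rose and fell at an adjusted p under 0.05, open points did not pass, black bars are list medians, and the dashed line is the median of all tested genes, 0.41. The medians of the mitochondrial lists lie left of both lines, with single members to the right, and all 32 matrix genes lie right of 0.

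Genes of glucose uptake and glycolysis were mostly higher as deposited. Of 21 measured, 14 rose and 3 fell (15 and 3 when adjusted over the list alone), or 6 and 5 after centring, and the median of 0.42 was close to that of all genes (camera adjusted p = 0.578, but 0.0391 with no filter on low values). The glucose transporter gene Slc2a1 rose from 2.567 ± 0.293 to 7.608 ± 0.712 RPKM, also after centring. Of 15 lipid genes that respond to PPAR receptors, 6 fell and 3 rose, or 9 and 2 after centring (camera adjusted p = 5.42e-05, lower). With an estimated correlation the adjusted p was 0.269. The lipases Lpl and Pnpla2 and the lipid droplet gene Cidea had log2 fold changes of -0.92, -1.28 and -0.72.

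Several genes that mark the fetal or stressed heart rose. Nppa, the atrial natriuretic peptide gene on chromosome 4 from 148000722 to 148002079, went from 119.0 ± 34.6 to 6676 ± 2480 RPKM (log2 fold change 5.78, SE 0.26, limma adjusted p = 2.99e-07). Its exons share 61.5% of their bases with Gm13054 on the opposite strand, whose reads could not be separated. Nppb rose from 127.9 ± 58.4 to 557.9 ± 43.3 RPKM, and skeletal actin Acta1 from 76.4 ± 17.7 to 933.4 ± 94.5. Of 17 fetal and stress-associated genes measured, 12 rose and 1 fell, or 9 and 2 after centring, with a median of 1.48. Myl4 and Myl7 are in this list and also in the list of atrial and epicardial markers. The list did not pass in camera (adjusted p = 0.173), but did with centring (adjusted p = 0.00575), quantile normalization (0.00169) and no filter on low values (0.00282). Myh7 did not pass, at 176.0 ± 31.9 against 153.9 ± 34.5 RPKM, and neither did Myh6, at 3383 ± 577 against 3509 ± 407, although Myh6 was lower after centring (-0.47, adjusted p = 0.0177). Tnni1, the fetal troponin I gene, was too low to test, at a mean of 0.652 against 0.194 RPKM. The adult troponin I gene Tnni3 fell from 3321 ± 333 to 1495 ± 153 RPKM. Of 22 genes of the adult sarcomere and energy transfer, 9 fell and 9 rose, or 14 and 2 after centring (camera adjusted p = 5.42e-05, lower). The adjusted p was 0.269 with an estimated correlation, and 0.477 after quantile normalization. Ventricular light chain Myl2 and adenylate kinase Ak1 fell, by -1.18 and -1.34, and the Z-disc gene Pdlim5 rose by 1.25 on the log2 scale. Markers of the atrium were uneven among these libraries, since Myl7 reached 112.9 RPKM in AAV-Cre library 3, against 41.7 to 52.8 in the others, and 26.2 in AAV-Luc library 2, against 2.95 to 9.88. Without those 2 libraries, 11626 genes passed the threshold, 10300 higher and 1326 lower. Whether atrial tissue contributed to the rises of Nppa and of the fetal list was not tested.

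Of 23 calcium handling genes, 14 rose and 5 fell, or 4 and 9 after centring (camera adjusted p = 0.351). The calcium pump gene Atp2a2 fell from 1799 ± 89.3 to 1351 ± 225 RPKM (log2 fold change -0.43, limma adjusted p = 0.00738). The calcium release channel Ryr2 did not pass, at 87.46 ± 9.40 against 92.81 ± 9.63 RPKM, but was lower with centring (-0.49, adjusted p = 0.00326). Potassium, sodium and gap junction channel genes went both ways, with 8 of 24 higher and 8 lower, or 6 and 13 after centring. Kcnd2 rose from 9.731 ± 1.32 to 45.51 ± 4.31 RPKM, and the channel subunit Kcne1 had a log2 fold change of 1.93. Kcnj2 did not pass (7.621 ± 0.723 against 6.426 ± 0.987 RPKM, adjusted p = 0.086), except without AAV-Luc library 3 (log2 fold change 0.30, adjusted p = 0.0442). The median of the channel list was -0.08 and its mean 0.13, and camera placed it lower than other genes (adjusted p = 0.00155). That call ended with an estimated correlation (adjusted p = 0.464), with centring (0.0518) and with quantile normalization (0.114), and fry, which does not compare a list with other genes, placed the list higher (adjusted p = 0.0383).

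**Figure D3:**
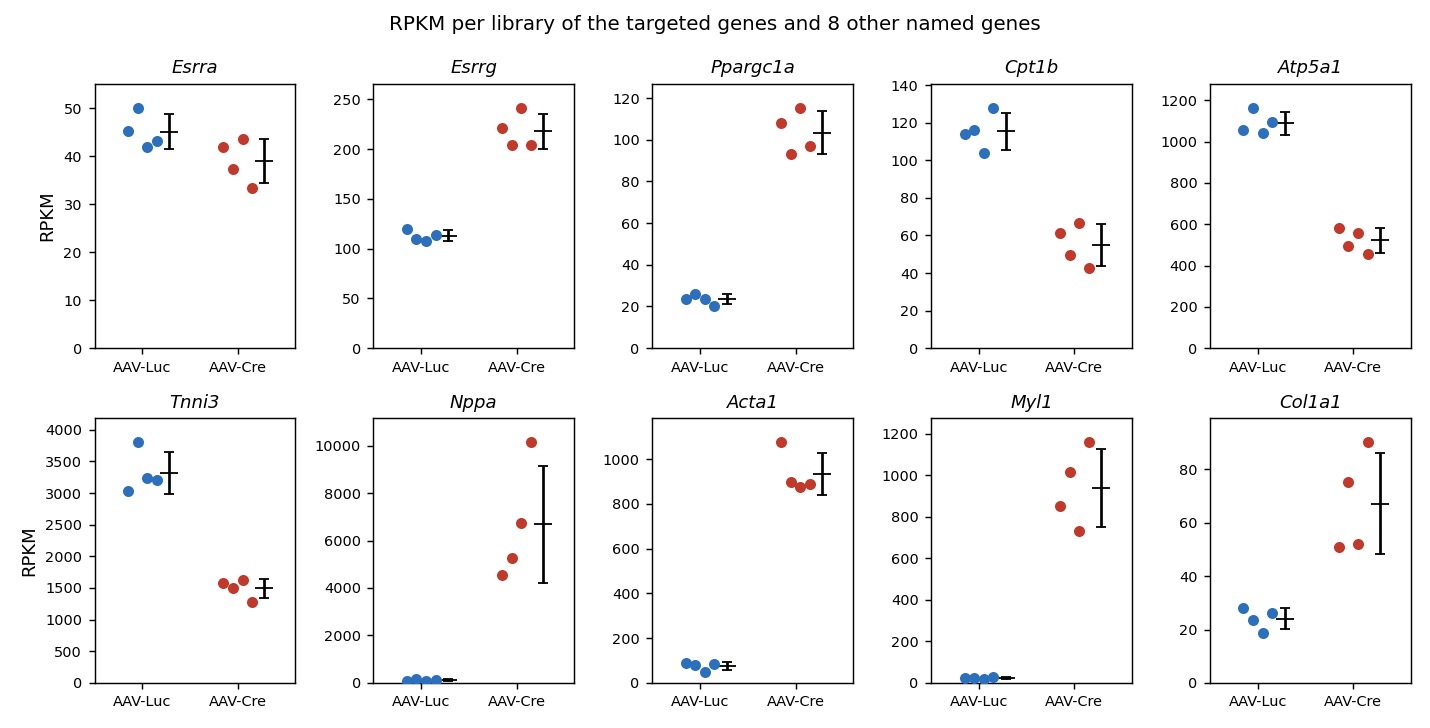
RPKM (y axes, each from 0) of the 2 targeted genes and 8 other genes in the 4 AAV-Luc libraries (blue) and the 4 AAV-Cre libraries (red), with the mean and SD in black. Esrra overlaps between the groups, and Esrrg is higher in every AAV-Cre library.

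The genes with the largest rises and falls were mostly outside these lists. After Nespas (45.14 ± 10.6 against 0.165 ± 0.058 RPKM) and Nppa came Grin2c, an NMDA receptor subunit, at 34.78 ± 4.28 against 0.202 ± 0.062, and the relaxin receptor Rxfp1, at 32.91 ± 2.34 against 0.259 ± 0.086. The melanocyte gene Mlana, the skeletal light chain Myl1, the neuronal nitric oxide synthase Nos1 and the aquaporin Aqp8 had log2 fold changes of 5.46, 5.33, 5.23 and 5.04. Nespas, Grin2c, Rxfp1, Mlana, Nos1 and Aqp8 were under 1 RPKM in every AAV-Luc library, so they passed the filter only through the AAV-Cre libraries. The size and rank of their fold changes depend on the pseudocount. Nespas lies on chromosome 2 from 174281237 to 174295436, antisense to Gnas, and 31.4% of its exon bases are also exon bases of Gnas, so its reads cannot be fully separated from that gene's. The 8 largest falls were milder. Lrtm1 (9.419 ± 1.92 against 44.63 ± 1.78 RPKM) and the calcium channel subunit Cacna2d3 (19.90 ± 3.90 against 91.17 ± 3.35) fell by -2.20 and -2.19 on the log2 scale. Lrtm1 lies on chromosome 14 from 29018208 to 29033645, inside Cacna2d3 and on the other strand, and they share no exon bases. The ratio of Lrtm1 to Cacna2d3 was 0.468 to 0.491 in all 8 libraries, so the rows are uncertain as separate genes and may largely count the same reads. The mitochondrial fission gene Mtfp1, the muscle ribosomal protein gene Rpl3l, Slc41a3, Plscr5, Gramd1b and Fndc5 had log2 fold changes of -2.00, -1.99, -1.96, -1.90, -1.89 and -1.87.

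Extracellular matrix genes rose in the libraries labelled AAV-Cre, together with markers of fibroblasts and macrophages. All 32 matrix and fibrosis genes rose, 25 of them also after centring, with a median log2 fold change of 1.36 (camera adjusted p = 0.00016, and adjusted p = 0.542 with an estimated correlation). The collagen gene Col1a1 went from 24.12 ± 3.96 to 67.14 ± 18.9 RPKM, the growth factor gene Ctgf from 25.88 ± 5.24 to 181.6 ± 30.8, and Tgfb3 and Timp1 had log2 fold changes of 2.66 and 3.28. All 12 fibroblast markers rose, 9 after centring (camera adjusted p = 0.0083, and adjusted p = 0.464 with an estimated correlation), and Mfap5, Pi16 and Wif1 had log2 fold changes of 1.91, 1.29 and 2.26. Of 16 macrophage markers 15 rose and none fell, or 13 and 1 after centring (median 1.11, camera adjusted p = 0.00411, and adjusted p = 0.464 with an estimated correlation), with Lyz2 at 186.1 ± 22.5 against 74.85 ± 2.74 RPKM and C1qc and Tyrobp also higher.

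Markers of other cell types moved less evenly. Of 15 endothelial markers, 4 rose and 1 fell (3 and 0 when adjusted over the list alone), or 1 and 10 after centring. Their median was 0.12, yet camera placed them lower than other genes (adjusted p = 0.0442), a call that ended with an estimated correlation (adjusted p = 0.542) and without any one of AAV-Cre libraries 1, 3 or 4 (0.0735, 0.111 and 0.0564) or AAV-Luc libraries 1 or 4 (0.0971 and 0.0555). It also ended without the 2 libraries of most Myl7 (0.0752) and with no filter on low values (0.283), and fry placed the list higher without a call (0.338). Vwf rose from 42.66 ± 8.0 to 107.9 ± 25.5 RPKM. Eng and Sox17 rose by 0.54 and 0.40 as deposited but did not pass after centring, where Sox17 was at -0.01. Of 12 smooth muscle and pericyte markers, 5 rose and 4 fell, or 5 and 7 after centring (camera adjusted p = 0.173, lower, with a median of 0.04 and a mean of 0.66). The contractile genes Cnn1 and Acta2 rose by 4.11 and 3.25, and Myh11 by 1.04. Of 10 skeletal muscle markers, 4 were high enough to test, and all 4 rose, 3 after centring. The rest, skeletal myosin genes among them, were too low to test, with means of at most 0.344 RPKM in either group. Mylpf went from 1.127 ± 0.276 to 8.789 ± 2.35 RPKM, with Atp2a1 and Tnni2 also higher. Atp2a1 passed the filter only through the AAV-Cre libraries. That list did not pass in camera (adjusted p = 0.122), but did with centring (0.00824), quantile normalization (0.0142) and mitochondrial genome reads taken out of the total (0.0478). Of 6 atrial and epicardial markers, 5 rose and none fell, or 4 and 1 after centring (camera adjusted p = 0.495), with log2 fold changes of 2.37, 2.38 and 2.74 for Dkk3, Myl4 and Myl7. None of 6 red blood cell markers was called as deposited and 4 fell after centring. Camera placed them lower (adjusted p = 0.0238), which was lost with an estimated correlation (adjusted p = 0.522), with centring (0.0518), and without AAV-Luc library 2 (0.0623) or AAV-Cre library 3 (0.111). It was also lost without both (0.216), with a mean of at least 5 RPKM (0.0597), with quantile normalization (0.35) and with quality weights (0.0823). Hba-a2, which has a near-identical copy, measured 1345 ± 244 against 1443 ± 312 RPKM, and Alas2 9.544 ± 1.80 against 10.13 ± 1.83. A single lymphocyte marker was high enough to test, Ighm, and did not pass at 4.410 ± 1.19 against 3.275 ± 0.761 RPKM, except without AAV-Cre library 3 (log2 fold change 0.51, adjusted p = 0.0318) or without the 2 libraries of most Myl7 (0.56, adjusted p = 0.0372). Neither of the 2 adipocyte markers tested passed, Cfd at 1.489 ± 0.619 against 1.566 ± 1.47 RPKM and Car3 at 2.209 ± 0.465 against 2.392 ± 1.75.

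Of 16 genes of the integrated and mitochondrial stress responses, 14 rose and none fell, or 9 and none after centring (median 0.97, camera adjusted p = 0.0343, and adjusted p = 0.464 with an estimated correlation). The serine synthesis gene Psat1 went from 1.216 ± 0.294 to 8.242 ± 0.805 RPKM, the transcription factor Atf4 from 20.90 ± 1.65 to 41.78 ± 1.84, and the proline synthesis gene Aldh18a1 from 16.15 ± 1.08 to 34.89 ± 3.60. The call of the list was also lost without AAV-Luc library 3 (adjusted p = 0.0512), without the 2 libraries of most Myl7 (0.0524), with a mean of at least 5 RPKM (0.0679) and with quality weights (0.0528). Of 17 unfolded protein response and chaperone genes, 10 rose and 3 fell, or 4 and 7 after centring (camera adjusted p = 0.499, lower, with a median of 0.40). Interferon response genes rose in 6 of 18 cases and fell in none (4 and 0 when adjusted over the list alone), or 3 and 1 after centring (camera adjusted p = 0.408). Of 15 proliferation genes 2 rose and none fell, or 1 and none after centring (camera adjusted p = 0.277).

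Genes that respond to handling and time of day were also measured. Of 12 immediate early genes, 8 rose and none fell, or 5 and none after centring (camera adjusted p = 0.406, but 0.0391 with no filter on low values), and Egr2, Egr3 and Ier3 had log2 fold changes of 2.13, 1.66 and 1.51. Egr2 and Egr3 passed the filter only through the AAV-Cre libraries. Of 14 circadian genes, 4 rose and 1 fell, or 3 and 5 after centring (camera adjusted p = 0.115, lower, with a median of 0.15, but 0.0346 without the 2 libraries of most Myl7). Arntl measured 13.62 ± 1.25 against 7.630 ± 1.68 RPKM, Clock 12.22 ± 1.65 against 7.002 ± 0.871, and Bhlhe41 3.754 ± 0.386 against 1.613 ± 0.248, all higher in AAV-Cre, also with centring. None of the 5 sex-linked transcripts passed (camera adjusted p = 0.123). With Xist as a covariate, Xist and Kdm5d passed as higher in AAV-Cre (log2 fold changes 0.47 and 0.39, limma adjusted p = 0.0447 and 0.0406). That covariate was cut from the values of Xist itself at 1 RPKM, which removes most of the spread of both genes by construction. These p-values are therefore not read as an effect of the label. Xist was above 1 RPKM in libraries 2 and 3 of each group and Y-linked transcripts, such as Uty and Kdm5d, were seen in libraries 1 and 4 of each, so that this difference was balanced. Of 16 housekeeping genes, 13 rose and 1 fell, or 7 and 1 after centring with a median of 0.60. Camera did not call them (adjusted p = 0.12), but did with centring (0.0427), quantile normalization (0.00383) and no filter on low values (0.00123). Of the 32 lists with at least 3 measured members, 18 passed in camera, 4 higher and 14 lower, none did with an estimated correlation, and 25 did by the directional p of fry. The 3 receptor genes, as a list, did not pass in camera (adjusted p = 0.231).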

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

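In the targeted and panel genes, 3 values lay apart from the other 3 of their group by Dixon's test, of 44 groups of values checked, where chance gives about 2.2. Cox7a1 was 817 RPKM in AAV-Luc library 2, against 565.9 to 602.4 in the others. Cox7a1 was 135.2 RPKM in AAV-Cre library 4, against 200.6 to 212.4. Acta1 was 1075 RPKM in AAV-Cre library 1, against 875.1 to 895.8. Of the tests below, those on the matrix genes and on Esrrg, and the abundant-gene test limited to protein-coding genes, were chosen only after the result was seen, and the planned abundant-gene test was judged void only after its value was known.

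Splitting the 8 libraries into 4 and 4 in all 35 ways, 1 split, the real one, gave as many as 12013 genes, and the highest other gave 10. For changes of 2-fold or more, 1 split gave as many as 1748, and the highest other gave 10. The real split thus ranked first of 35 for both counts, which is the most this test can show and does not exclude chance. In every other split the difference between the labels adds to the spread within groups. Low counts there were fixed in advance and do not measure what chance would give. The highest other split was the one by Xist, which follows sex rather than group. For the count of gene lists in camera, 13 of the 35 splits gave 18 or more, with 20 as the highest other. Of these 13 splits, 11 placed 3 libraries of one group with 1 of the other, and such splits keep part of the difference between the labels. Splits with 2 libraries of each group on either side balance the labels, and the highest of those gave 19 lists. The share of splits also met the bound set beforehand for chance as an explanation. The count of 18 lists therefore does not by itself show a difference between the labels.

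The median log2 fold change of all tested genes was 0.41 rather than 0. A smaller share of mitochondrial genome reads in AAV-Cre may account for part of this shift. With those reads taken out of each total the median was still 0.245, above the bound of 0.1 set for that share as the whole cause. However, the level of the share is uncertain, and reads of the 7 pseudogene rows that match mitochondrial genes stayed in the totals. Whether the share accounts for the whole shift therefore cannot be told. A planned test that also took out the 200 nuclear genes with most reads gave 1.42, and a narrower version with protein-coding genes gave 1.21. Both values pass the bound of 0.1 set against that explanation, but both tests were void: RPKM multiplied by merged exon length summed to 196.8 to 231.1% of each library, so the shares taken out were too large. Whether a lower share of abundant nuclear transcripts completes the shift, or most genes rose per cell, stays open.

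Matrix, fibroblast and macrophage genes were higher in the libraries labelled AAV-Cre. The shift of all genes does not account for it, since 25 of the 32 matrix genes were still called as higher with each library centred on its median. A lower share of cardiomyocyte RNA as the whole cause would raise the markers of every other cell type alike. The median of fibroblast markers exceeded that of endothelial markers by 1.07 on the log2 scale (permutation of genes between the lists, p = 0.00086, and genes are not independent). Both medians were known when this comparison was chosen, so it is a description rather than a test. The difference is not what a lower share alone would give, but such a share as part of the cause stays possible. Whether there were more fibroblasts and macrophages or more expression in each cell stays open, and no biological explanation was tested.

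Esrrg was higher in the libraries labelled AAV-Cre, although the vector targets it. The shift of all genes is not the whole cause, since Esrrg kept a log2 fold change of 0.54 (SE 0.08) with centring. Transcripts that continue outside the floxed exons could give this value, but the ratio of 1.93 is over the whole gene, and no value per exon was at hand. An exchange of the column names between the groups runs against the lower values of all 24 tricarboxylic acid cycle genes and, with centring, of Esrra (-0.62), if these receptors activate such genes as their known role would have it. It is not excluded by that background alone, as 0 rows carry the vector's own genes, and neither explanation can be told apart from a rise of the gene itself.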

How the results depend on the processing

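The alternatives named here as added were chosen after seeing the data: mitochondrial genome reads taken out of the total, protein-coding genes only, Xist as a covariate, and leaving out the library with most Myl7 in each group. Esrrg kept its direction and its call under every alternative run, and so did Esrrb, except that a mean of at least 5 RPKM left it out. No paired analysis was possible because the columns carry no sample titles, so the numbers in the titles could not be joined to them. The fit with the title number as a replicate block and the fits of its 2 subsets of libraries were not run for that reason. The total of genes past the threshold was 7705 with a mean of at least 5 RPKM, where fewer genes were tested, 7648 with quantile normalization and 7527 with centring. Those that rose numbered 6607, 3810 and 3578, and with the last 2 settings 3838 and 3949 fell. Calls of 2-fold or more numbered 1005 with a mean of at least 5 RPKM and 1153 with protein-coding genes only, as fewer genes were tested. Of these, 792 and 941 rose, while 558 rose and 679 fell with quantile normalization and 560 rose and 737 fell with centring. With mitochondrial genome reads taken out, 448 fell by 2-fold or more. Both normalizations remove the shift of the median by construction. The count of lists in camera was 0 with an estimated correlation, where the lowest adjusted p was 0.0782. Esrra passed the threshold at -0.56 with quantile normalization, -0.62 with centring, -0.28 without mitochondrial and haemoglobin genes, -0.22 with quality weights and -0.39 without mitochondrial genome reads. Rescaling lowered Esrrg alike, from 0.95 to 0.54 with centring, 0.87 without mitochondrial and haemoglobin genes and 0.76 without mitochondrial genome reads. In those settings the call of Esrra follows from the scaling, and which scaling is right was not tested. For the other settings the cause was not tested. Leaving out each library in turn, Esrra ranged from -0.26 to -0.14 and passed only without AAV-Cre library 3 (-0.26, adjusted p = 0.0338), Esrrb from -0.53 to -0.33, and Esrrg from 0.89 to 0.98. Over the same fits, the genes past the threshold ranged from 10645 to 11619, with 9315 to 10352 higher and 1267 to 1530 lower. Those of 2-fold or more ranged from 1312 to 1857, with 1057 to 1603 higher and 254 to 317 lower, and the lists from 16 to 18. Of the other named genes that had passed the threshold, Sox17 alone changed sign, at -0.027 with quantile normalization and -0.012 with centring. In 2153 values of named genes under the alternatives, 4 calls ended with the direction kept, the 2 of Sox17 above ended with a change of sign, and 14 were gained, in 11 genes. Apart from the estimated correlation and fry, 22 calls of 6 lists ended and 12 calls of 6 lists were gained, of 662 compared, and none reversed. Fry, which does not compare a list with other genes, turned 7 lists from lower in camera to higher: receptor genes (adjusted p = 0.0374), calcium handling (0.000529), channels (0.0383), endothelial markers (0.338), smooth muscle and pericyte markers (0.0024), the unfolded protein response (8.71e-05) and circadian genes (0.00629). Of these, camera had called the channel and endothelial lists. Fry also ended the calls of 3 lists, mitochondrial regulators (0.383), adult sarcomere (0.194) and red blood cells (0.73), and called 6 others anew. With 4 libraries per group, 64% of simulated changes of 0.5 on the log2 scale were found. Only 50 of 16385 genes changed at each size there, against 12013 that passed in the data, which made the simulated unadjusted cut stricter. The 64% therefore does not measure how many such changes were found here, and small changes can still be missed.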

Other observations

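The gene groups and pairs here were all chosen after the data were seen. Cytosolic ribosomal protein genes rose in the libraries labelled AAV-Cre in all 75 measured cases, and in 61 with each library centred on its median, with a median log2 fold change of 0.83 (camera adjusted p over these 9 groups = 2.45e-07). With an estimated correlation the adjusted p was 0.45. Cytosolic aminoacyl-tRNA synthetase genes rose in 17 of 17 cases, 5 after centring, while of 17 mitochondrial ones 2 rose and 4 fell, or none and 15 after centring. Their camera adjusted p was 0.006, higher, and 0.000253, lower (adjusted p = 0.424 and 0.189 with an estimated correlation). Of 11 genes of ubiquinone synthesis 6 fell and 2 rose, or 9 and 1 after centring (camera adjusted p = 1.14e-05, lower, and adjusted p = 0.204 with an estimated correlation). Of 23 genes of mitochondrial import 13 rose and 8 fell, or 1 and 10 after centring (camera adjusted p = 0.0054, lower, and adjusted p = 0.424 with an estimated correlation).

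Of 11 tubulin genes, 8 rose and 2 fell, or 8 and 3 after centring (camera adjusted p = 0.534). Intermediate filament genes rose in 7 of 8 cases and 4 after centring, when 1 fell (camera adjusted p = 0.0422, and adjusted p = 0.424 with an estimated correlation). Annexin and S100 genes rose in 14 of 16 cases, and in 11 after centring, when 1 fell (camera adjusted p = 0.0283, and adjusted p = 0.424 with an estimated correlation). Of 37 proteasome genes 30 rose and none fell, or 5 and 8 after centring. Camera placed them higher than other genes (adjusted p = 0.0422, and adjusted p = 0.45 with an estimated correlation), although their median of 0.34 lay below the 0.41 of all genes and was -0.07 after centring.

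A ratio of 2 genes within a library does not depend on the scaling of that library, apart from the pseudocount. A hypothesis is that isoforms enriched in heart or skeletal muscle may be lower relative to their paralogs in AAV-Cre. It was not open to a test here, because the values of some members were known when the 16 pairs were chosen. As a description, the ratio was lower in every AAV-Cre library than in every AAV-Luc library in 14 of the 16 pairs, with a median difference of -0.90 on the log2 scale. One of the 14 is Ldhb to Ldha (-1.84), the heart form against the form of skeletal muscle, which does not follow the contrast of muscle and other tissues, and 13 of 15 pairs remain without it. Among the others, the difference was -3.66 for Rpl3l to Rpl3, -2.29 for Eef1a2 to Eef1a1, -1.81 for Slc2a4 to Slc2a1 and -1.64 for Cpt1b to Cpt1a. The ratio of Pgam2 to Pgam1 went the other way (0.64), and that of Slc25a4 to Slc25a5 overlapped between the groups (-0.16). Some of these pairs share sequence, and some paralogs are also expressed by other cell types whose markers rose, so the ratios may reflect a changed mixture of cells as well as expression in cardiomyocytes.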
